A study of Mus musculus with 6 samples.

How the data were processed

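The 6 libraries from the septal area of wild type mouse brain were measured with Chromium Single Cell 3' v3 chemistry, per the submitters' protocol text, in which droplets give each nucleus a barcode and each RNA molecule a unique molecular identifier (UMI). The series title speaks of single nuclei while the protocol text speaks of single cells, and the molecule label is polyA RNA. Mitochondrial UMIs made up 0.047 to 0.0706% of all UMIs and Malat1, a nuclear RNA, 3.32 to 3.82%, and the barcodes are called nuclei here on the word of the title. Age, sex, number of animals, dissection and batch are not given in the sources used here. The 6 libraries are treated as replicates 1 to 6 of 1 group.

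The deposited values are raw UMI counts per gene and barcode, which the authors made with Cell Ranger and STAR, per the submitters' processing notes. Those notes give Cell Ranger 3.1.0, while the file headers of the deposited count matrices give version 5.0.0, and which of them made the counts could not be told. The count matrices as deposited held only barcodes already called as cells, with no empty droplets. The annotation held 32285 genes, and the genome build is not given in the sources used here. Gene names and identifiers were taken from the deposited gene tables, and the reference at hand was not used here. Whether intron reads were counted is not given in the sources used here, and for nuclei this choice affects the level of long genes. Reads and unfiltered barcodes were not analysed here.

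Replicates 1 to 6 held 9788, 10471, 7393, 11134, 9345 and 7406 barcodes with 83494028, 95175260, 70183544, 88515861, 82782773 and 73271971 UMIs. Nuclei with fewer than 500 detected genes (914 barcodes) or more than 5% mitochondrial UMIs (27) were removed, as were predicted doublets (4210), leaving 8792, 9587, 6715, 10014, 8424 and 6866 nuclei. The median UMI count of kept nuclei was 5295.5, 5745, 6402, 4706.5, 5427.5 and 6502.5. Pairs of libraries shared at most 0.433% of the barcodes of the smaller one, with a Pearson correlation of log2 CPM (counts per 1e6 UMIs) of 0.998 to 0.999 and a chi-square per gene of 7.09 to 22.5, so no library was a copy of another. Doublets were called within each library by adding the counts of a pair of random barcodes, embedding real and added barcodes in 30 principal components and taking the share of added ones among 50 neighbours. The expected rate was 0.8% per 1000 barcodes. Only 43.8 to 60.7% of the added doublets reached the threshold, so doublets remain among the kept nuclei.

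Clustering used 2000 genes with the highest dispersion of depth-scaled counts within bins of mean level, averaged over samples. Mitochondrial, ribosomal and sex-linked genes, Malat1 and the 271 genes of the 13 lists tested later were left out of them. Counts were scaled to 10000 per nucleus, log-transformed, scaled per gene and clipped. The first 40 principal components, exact 20 nearest neighbours, a shared-neighbour graph with Jaccard weights and Leiden at resolution 1 with seed 1 gave 48 clusters. No correction between samples was applied.

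Clusters were named from 129 marker genes of 22 classes fixed before the data were examined, 66 of which were also clustering features. A marker counted as detected at no less than 3 CPM and 2 times the lower quartile of clusters, with 1 CPM added. A non-neuronal class was present with 3 detected markers and a median marker level of 0.25 of the highest cluster, the neuron class by that level alone, and either had to reach 0.4 of the best mean log2 marker fold. A cluster with a pair of unrelated classes present stayed unnamed. A cluster with neuroblast and neuron markers was called a neuron when its neuroblast level lay under 0.3. Neurons took the name of the highest mean marker fold among types with 3 detected markers, with glutamatergic names reserved for clusters in which Slc17a6 or Slc17a7 stood 8 times above the lower quartile and above the GABAergic markers. The 10 leading genes by fold over other clusters (pseudocount 10 CPM, level of no less than 30 CPM) had to hold no more markers of another class than of its own. A cluster with a median UMI count under 1/3 of that of its samples and no marker among its leading genes also stayed unnamed. These thresholds and the rule on leading genes were set after the clusters were seen, and the rule moved cluster 5 (1819 nuclei) from the medial septum-like and cluster 20 (943 nuclei) from the lateral septum-like class to other GABAergic-like neurons. Names end in "-like" because they rest on markers and not on location. In all 12 clusters stayed unnamed and entered no comparison.

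The 5 comparisons between classes, the tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. Raw counts were summed per sample and class where a class had no fewer than 10 nuclei in a sample, and no fewer than 4 samples had to hold both classes. Nuclei per sample ranged over 2555 to 3920 GABAergic-like, 223 to 376 glutamatergic-like, 1768 to 2822 lateral septum-like, 51 to 108 medial septum-like, 232 to 555 spiny-like, 37 to 85 cholinergic-like, 2807 to 4296 other neurons, 312 to 477 precursor-like and 976 to 1486 oligodendrocyte-like. Median UMIs per sample ranged over 9996 to 14050, 9526 to 12305, 10569 to 14443, 12741 to 18199, 7803 to 11757, 8401 to 13225.5, 9986 to 13872, 5176 to 7047.5 and 2687 to 3894 in the same order. All 6 samples entered every comparison. edgeR's quasi-likelihood test was run with TMM factors, filterByExpr and the sample as a block, and p-values were adjusted by Benjamini-Hochberg at 0.05. The adjustment ran over tested genes that were neither clustering features nor naming markers, because classes drawn from the same counts inflate tests of the genes that drew them. Genes correlated with the features can still carry part of that inflation. Standard errors of log2 differences were taken as the absolute difference over the square root of the F statistic, and CPM values as mean ± SD over samples.

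Lists were tested with limma's camera on log2 CPM (prior count 2) at an inter-gene correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists with 3 or more tested members. The count "adjusted over the list alone" applies Benjamini-Hochberg to the members of 1 list. From each list the gene with the largest change in each direction was named, among those with adjusted p under 0.05 and the same sign in every sample. The 3 largest changes in each direction among all tested genes with a symbol other than Gm or Rik names were added. A named gene had to reach 10 CPM in its higher class. Some genes that met this rule are not reported here. Esr1, Nts, Sst, Drd3, Oprm1, Crhr2 and Oxtr were named in lateral septum comparisons whatever their values. Where a class had 0 counts of a gene a floor of 3 counts was used, and for 1 to 3 counts an exact 95% interval of the ratio was derived from the binomial distribution.

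Free RNA carried into droplets was estimated as the pooled profile of each library times the median ratio of markers of other lineages in a class, with 16 markers for neurons and 13 for glia at no less than 10 CPM in the pooled profile. The ratio was 0.143 ± 0.018 in GABAergic-like, 0.13 ± 0.027 in glutamatergic-like, 0.141 ± 0.0169 in lateral septum-like, 0.0974 ± 0.0175 in medial septum-like, 0.141 ± 0.0222 in spiny-like and 0.118 ± 0.0288 in cholinergic-like neurons (SD, n = 6). It was 0.141 ± 0.0164 in other neurons, 0.284 ± 0.0486 in precursor-like and 0.154 ± 0.0224 in oligodendrocyte-like nuclei (SD, n = 6). Without empty droplets the estimate cannot be checked, and no count was corrected by it.

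Alternatives fixed in advance were 1000 genes per nucleus, no mitochondrial limit, doublets kept, clustering resolutions 0.5 and 2, features centred per sample, lists left in the clustering, RLE factors, DESeq2's Wald test, no low-count filter, no replicate block, nuclei thinned to 2000 UMIs and each replicate left out in turn. A pair was added after the data were seen, namely classes named without the rule on leading genes and genes at no less than 3 times the free RNA estimate. Label swaps exchanged the names of both classes within samples, 32 ways up to mirror image. Each sample was compared with the other 5 for class shares and for differences of log2 CPM with 1 CPM added. Clustering and the gene test were each run on simulated data. In the first, 3000 simulated nuclei of 10 profiles gave 10 clusters at an adjusted Rand index of 1. These profiles were the summed counts of the largest named clusters, without doublets or variation within a cluster beyond counting. Such an outcome was close to assured and does not bear on how stable the real clusters are. Naming was not simulated. In the second, with classes known and 200 genes changed per comparison, 56 of 809 passing genes were unchanged ones (6.92%), above the nominal 5%. It does not cover inflation from classes drawn from the same counts. Of genes changed 1.5-fold, 61.2, 49.3, 62.7, 28.4 and 71.6% were recovered in the order of the comparisons, and of those changed 4-fold 98.5, 93.9, 100, 66.7 and 100%. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.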

Results

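Nuclei of the mouse septal area, a forebrain region whose lateral part holds mostly inhibitory neurons and whose medial part holds inhibitory, cholinergic and glutamatergic neurons, were profiled by droplet RNA sequencing. The 6 samples were wild type and form 1 group. The samples held 9788, 10471, 7393, 11134, 9345 and 7406 barcodes for replicates 1 to 6, with total counts of 83494028, 95175260, 70183544, 88515861, 82782773 and 73271971 unique molecular identifiers (UMIs). After filters on detected genes, mitochondrial share and predicted doublets, 50398 of 55537 barcodes (90.7%) were kept, with a median of 4706.5 to 6502.5 UMIs per nucleus across samples. The labels name no contrast between samples, so cell classes were compared within samples, and no question behind these comparisons is given in the sources used here. Because nothing states that the samples are separate animals, each p-value measures only the spread between these samples, which may be technical.

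Neurons made up 41.6 ± 3.19% (SD, n = 6) of the kept nuclei, and GABAergic-like neurons alone 37.3 ± 2.98% (SD, n = 6). The most abundant class was lateral septum-like GABAergic neurons at 26.6 ± 2.17% (SD, n = 6; 13393 nuclei in 14 clusters), with Trpc4, a cation channel gene, at 795 ± 9.33 CPM (counts per 1e6 UMIs) and Dgkg, a diacylglycerol kinase gene, at 886 ± 23.7 CPM (SD, n = 6). Striatal medium spiny-like neurons, with Rgs9 at 217 ± 47.3 CPM, reached 4.24 ± 0.874% of nuclei, and subcortical glutamatergic-like neurons, with the vesicular glutamate transporter Slc17a6 at 159 ± 9.42 CPM, reached 3.57 ± 0.733% (SD, n = 6). Medial septum-like GABAergic neurons as drawn made up 0.902 ± 0.154% (SD, n = 6; 460 nuclei). This share moved to 2.81% with no mitochondrial limit, 6.19% at clustering resolution 0.5, 2.94% at 2.0 and 2.75% with the gene lists left in the clustering, and without the rule on leading genes 1819 nuclei would join. Cholinergic-like neurons were rare at 0.622 ± 0.12% (SD, n = 6; 318 nuclei). In these, the choline acetyltransferase gene Chat stood at 152 ± 39.5 CPM. Cortical glutamatergic-like neurons, with Slc17a7 among their leading genes, made up 0.15 ± 0.095% (SD, n = 6), and other GABAergic-like neurons 5.53 ± 0.781%, a share that fell to 1.87% at clustering resolution 0.5 and 2.83% with the lists left in the clustering.

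Among glia, astrocyte-like nuclei with the glutamate transporter Slc1a2 at 5654 ± 231 CPM made up 20.9 ± 1.17% (SD, n = 6). Oligodendrocyte-like nuclei with the myelin gene Mog at 809 ± 38.2 CPM made up 14.0 ± 1.73% (SD, n = 6). Oligodendrocyte precursor-like nuclei, with the growth factor receptor Pdgfra at 683 ± 32.7 CPM, made up 4.71 ± 0.4%, and microglia-like nuclei 2.03 ± 0.376% (SD, n = 6). Ependymal-like nuclei, with the ciliary dynein gene Dnah12 at 3757 ± 85.5 CPM, reached 5.71 ± 1.15%, endothelial-like nuclei 1.77 ± 0.23%, pericyte or smooth muscle-like nuclei 1.07 ± 0.095% and fibroblast-like nuclei 0.298 ± 0.075% (SD, n = 6). A neuroblast-like class at 0.586 ± 0.083% had the cell-cycle genes Top2a and Mki67 among its leading genes and held 1.505% at clustering resolution 0.5. A further 12 clusters with 7.32 ± 0.898% of nuclei stayed unnamed (SD, n = 6), against 19 of 55 clusters with doublets kept. These marker genes served to name the classes and are not results, and shares depend on which nuclei were released and captured.

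**Figure D1:**
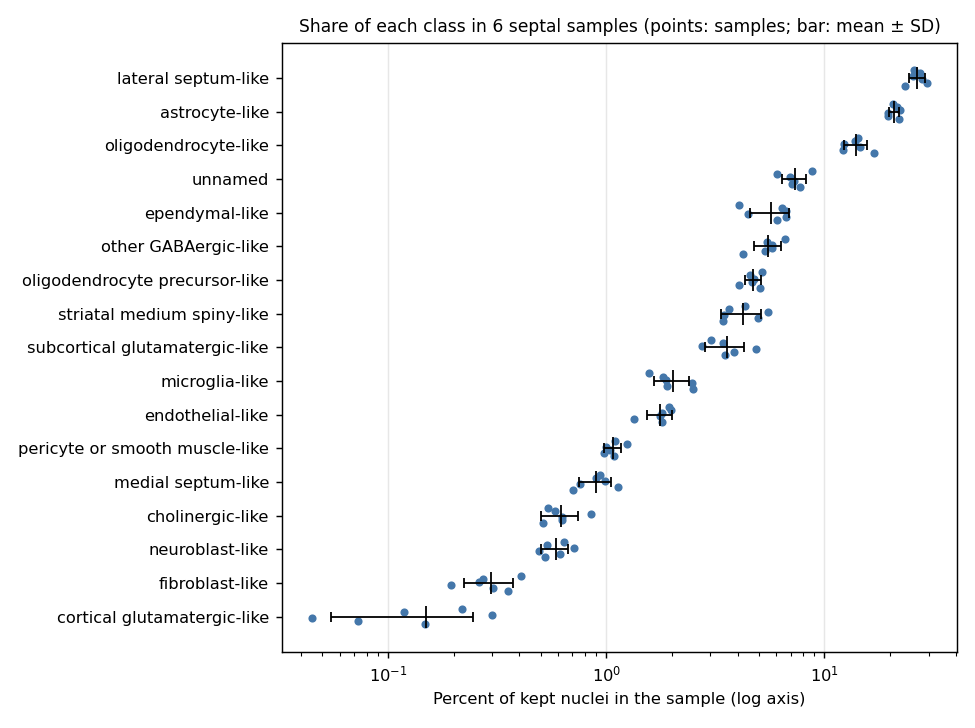
Share of kept nuclei per cell class in percent on a log axis, with 1 point per sample and a bar for the mean ± SD of 6 samples. Lateral septum-like neurons hold 26.6%, astrocyte-like nuclei 20.9% and oligodendrocyte-like nuclei 14.0%, against 0.902% for medial septum-like and 0.622% for cholinergic-like neurons. The medial septum-like share moves to between 2.75 and 6.19% under 4 other settings and stays at 0.909% with features centred per sample and 0.874% with doublets kept.

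GABAergic-like and glutamatergic-like neurons differed in Eomes (ENSMUSG00000032446), a T-box transcription factor gene of glutamatergic lineages, which stood at 33.3 ± 10.4 CPM in glutamatergic-like and 0.163 ± 0.0684 CPM in GABAergic-like neurons (SD, n = 6). The homeobox gene Uncx (ENSMUSG00000029546) stood at 21.9 ± 9.09 against 0.16 ± 0.0678 CPM. Dlx1, a homeobox gene of forebrain inhibitory neurons, was higher in GABAergic-like neurons at 15.7 ± 1.45 against 1.40 ± 0.284 CPM. So was Met, the hepatocyte growth factor receptor gene, at 23.2 ± 1.82 against 2.09 ± 0.592 CPM (SD, n = 6). The presynaptic adhesion gene Nrxn3 stood at 10400 ± 201 CPM in GABAergic-like and 3546 ± 207 CPM in glutamatergic-like neurons. The receptor phosphatase gene Ptprd stood at 1288 ± 68.4 against 11850 ± 2341 CPM (SD, n = 6). Duox2, an oxidase gene, was higher in glutamatergic-like neurons by a log2 difference of -7.56 ± 0.31 (SE, GABAergic minus glutamatergic). The collagen gene Col6a3 was higher in GABAergic-like neurons by 3.61 ± 0.23 (SE, n = 6). The glutamatergic-like class pooled clusters whose shares differed by sample, and cluster 13 made up 1.15% of nuclei in replicate 4 and 1.53% in replicate 6 against no less than 2.28% in the others. These same libraries had the smallest differences for Eomes, Uncx, Dlx1, Nrxn3, Duox2 and Ptprd, and also for Thrb, Htr1f, Chrm2, Chrm3, Grm5, Grm8, Gabra4, Cacna1e, Dagla and Egr3. The make-up of the class may enter all these values.

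Of 20 tested monoamine receptor genes, 13 were higher in GABAergic-like neurons, 4 in glutamatergic-like neurons and 3 did not pass (14 and 4 adjusted over the list alone). The serotonin receptor Htr1f stood at 299 ± 14.8 against 63.9 ± 19.6 CPM and Htr2a at 8.40 ± 1.18 against 33.6 ± 5.04 CPM (SD, n = 6). Steroid and thyroid hormone receptor genes divided 6 to 1 with 1 not passing (also 6 and 1 adjusted over the list alone). Thrb led at 506 ± 19.1 against 164 ± 65.5 CPM. Among neuropeptide precursor genes, 8 of 11 were higher in GABAergic-like and 2 in glutamatergic-like neurons. The latter were Adcyap1 at a log2 difference of -2.36 and Gal at -1.76, named after their values were seen. Neuropeptide receptor genes divided evenly, 11 and 10 of 31. The orexin receptor Hcrtr2 stood at 12.4 ± 2.25 against 87.0 ± 9.63 CPM. Crhr2, a receptor for corticotropin-releasing peptides, stood at 13.9 ± 0.965 against 1.38 ± 0.456 CPM (SD, n = 6). For acetylcholine receptors the division was 3 and 3 of 8 (4 and 3 adjusted over the list alone). Chrm3 was higher in GABAergic-like neurons at 610 ± 14.4 against 162 ± 49.2 CPM. Chrm2 was higher in glutamatergic-like neurons at 520 ± 37.4 against 191 ± 6.45 CPM (SD, n = 6).

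Glutamate receptor genes were higher in GABAergic-like neurons in 12 and in glutamatergic-like neurons in 6 of 25 cases. Grm5 stood at 4736 ± 136 against 1337 ± 191 CPM and Grm8 at 1074 ± 52.7 against 2398 ± 543 CPM (SD, n = 6). GABA receptor genes divided 9 to 6 of 16, with Gabra4 at a log2 difference of 0.84 ± 0.07 (SE, n = 6). Potassium and HCN channel genes divided 9 to 13 of 32 (10 and 13 adjusted over the list alone). Kcnn3 stood at 1.63 ± 0.06 and Kcnh8 at -1.57 ± 0.08 on the log2 scale, and in thinned nuclei the list turned to 12 and 10 of 30. Sodium and calcium channel genes divided 6 to 10 of 21 (6 and 11 adjusted over the list alone). Cacna1e stood at 1.56 ± 0.12 (SE, n = 6). Synaptic adhesion genes divided 13 to 10 of 28, where the list's median, mean and test differed in sign. Of the cholesterol synthesis list, 16 of 20 genes were higher in glutamatergic-like neurons and 4 did not pass (18 adjusted over the list alone). Of 13 immediate early genes, 5 were higher in GABAergic-like neurons and 8 did not pass. Egr3 led at 11.8 ± 1.76 against 3.34 ± 2.60 CPM. Of 6 endocannabinoid genes, 3 were higher in GABAergic-like neurons. Dagla led at 43.5 ± 2.78 against 25.8 ± 4.03 CPM (SD, n = 6).

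In all, 5980 of 15718 tested genes passed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted threshold of 0.05, 2978 higher in GABAergic-like and 3002 higher in glutamatergic-like neurons. Which side held more genes depended on scaling and filter, with 3105 against 2849 by RLE factors, 2859 against 2592 by DESeq2 and 3468 against 2498 with no filter on low counts. Adjusted p was 2.1e-11 for Eomes, 9.6e-11 for Nrxn3 and 3.1e-05 for Egr3 in that test, and every gene named in this comparison had its direction in 6 of 6 samples. In limma's camera test 5 lists passed at the preset correlation, with adjusted p of 0.0134 for monoamine receptors, steroid receptors and immediate early genes, 0.0465 for neuropeptide precursors and 3.3e-06 for cholesterol synthesis. All 5 calls were lost with an estimated correlation, where adjusted p = 0.431 with an estimated correlation for monoamine receptors and adjusted p = 0.351 with an estimated correlation for the other 4 lists.

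Lateral septum-like and medial septum-like GABAergic neurons differed in Casz1, a zinc finger transcription factor gene (ENSMUSG00000028977), at 4.09 ± 0.484 CPM in lateral and 198 ± 28.7 CPM in medial septum-like neurons (SD, n = 6). The axon guidance receptor Robo3 stood at 0.332 ± 0.162 against 45.6 ± 11.4 CPM and the sarcomere protein gene Mypn at 0.378 ± 0.131 against 13.5 ± 2.21 CPM. In the other direction, the kinase gene Styk1 was at 26.8 ± 0.968 against 0.968 ± 0.308 CPM. Adam18, a metalloprotease family gene, stood at 16.1 ± 1.26 against 0.464 ± 0.544 CPM (SD, n = 6). Calcr, the calcitonin receptor gene, had no count in medial septum-like neurons of any sample and was at least 33.0-fold higher in lateral septum-like neurons, against a floor of 3 counts over the group. Higher in medial septum-like neurons were Kcnc2, a potassium channel gene of fast-spiking neurons, at 752 ± 84.1 against 167 ± 7.67 CPM and the orexin receptor Hcrtr2 at 106 ± 29.2 against 5.75 ± 1.07 CPM (SD, n = 6).

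Of the genes chosen for this region in advance, Esr1, the estrogen receptor alpha gene, was at 18.5 ± 1.19 CPM in lateral and 4.6 ± 1.51 CPM in medial septum-like neurons (SD, n = 6), a direction that turned at clustering resolution 0.5 (-0.70 on the log2 scale) and without the rule on leading genes (-0.84). The neurotensin gene Nts stood at 10.8 ± 4.19 against 0.929 ± 1.09 CPM and the dopamine receptor Drd3 at 11.9 ± 1.85 against 3.35 ± 2.54 CPM (SD, n = 6). The mu opioid receptor Oprm1 was higher in medial septum-like neurons at 68.7 ± 6.38 against 43.3 ± 2.21 CPM. Oprm1 turned with no mitochondrial limit (0.18), at resolution 2.0 (0.09) and with lists left in the clustering (0.11). The somatostatin gene Sst was low at 3.54 ± 0.582 against 1.40 ± 1.36 CPM. Its log2 difference was 1.24 ± 0.42 (SE, n = 6; edgeR adjusted p = 0.0192, higher in 5 of 6 samples). The call of Sst was lost without replicate 3 (1.11), replicate 4 (1.10) or replicate 6 (0.93), where most of the difference stayed, and without the rule on leading genes, where it shrank to 0.18. Crhr2 at 8.36 ± 0.677 against 6.49 ± 3.62 CPM did not pass (edgeR adjusted p = 0.185, log2 difference 0.40 ± 0.24 SE, higher in 5 of 6 samples) as the classes were drawn. Crhr2 passed without replicate 1 (0.71), with no mitochondrial limit (1.17), at resolution 0.5 (1.24) and 2.0 (1.29), with lists left in the clustering (1.07) and without the rule on leading genes (2.04). A cluster that the naming rule kept out of both classes held 52.9% of the Crhr2 counts found in this cluster and the 14 lateral septum-like clusters together. The oxytocin receptor Oxtr at 1.74 ± 0.391 against 1.28 ± 0.672 CPM did not pass either (edgeR adjusted p = 0.649, log2 difference 0.30 ± 0.46 SE, higher in 5 of 6 samples). Oxtr passed with no mitochondrial limit (0.90), at resolution 0.5 (1.05) and 2.0 (1.03), with lists left in the clustering (0.98) and without the rule on leading genes (0.92). Both non-calls thus depend on how the classes were drawn.

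**Figure D2:**
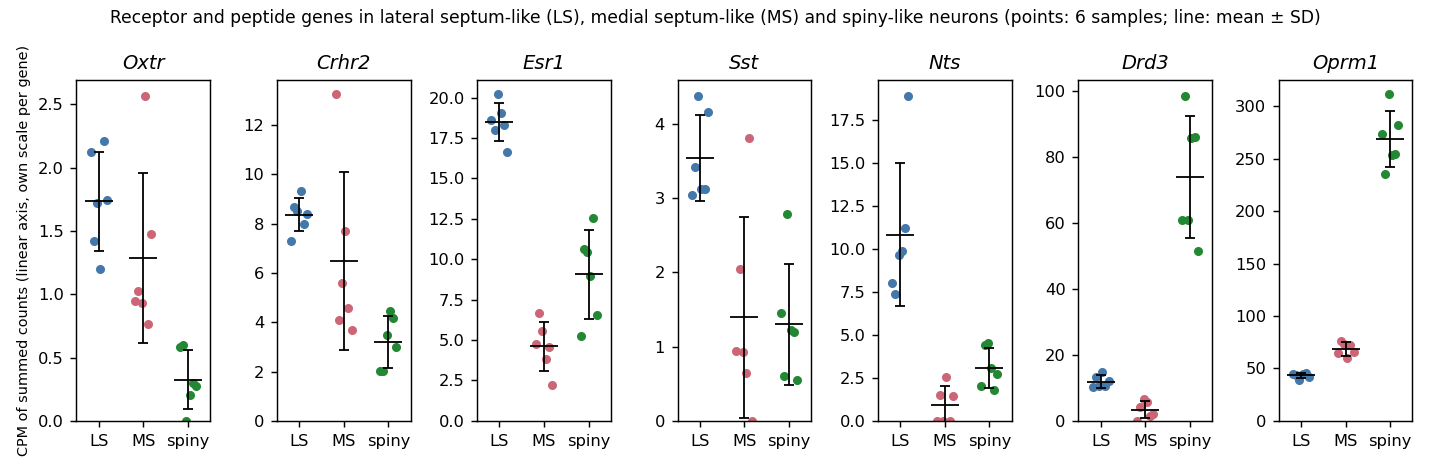
Level of 7 receptor and peptide genes in CPM of summed counts on a linear axis per gene, in lateral septum-like (LS), medial septum-like (MS) and striatal medium spiny-like (spiny) neurons, with 1 point per sample and a line for the mean ± SD of 6 samples. Esr1 averages 18.5 CPM in LS, 4.6 in MS and 9.07 in spiny neurons, while Oprm1 averages 43.3, 68.7 and 268 CPM. The LS and MS order of both genes turns when the medial class is drawn otherwise, to -0.70 on the log2 scale for Esr1 at clustering resolution 0.5 and 0.09 for Oprm1 at 2.0.

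Immediate early genes, which neurons transcribe soon after activity, were higher in lateral septum-like neurons in 11 of 12 cases with 1 not passing. Egr3 led at 13.3 ± 2.78 against 1.29 ± 0.827 CPM (SD, n = 6). Cholesterol synthesis genes went the other way, with 15 of 20 higher in medial septum-like neurons and 5 not passing (18 adjusted over the list alone). Among GABA receptor genes, 10 of 16 were higher in lateral and 3 in medial septum-like neurons. Gabrg1 stood at 157 ± 9.87 against 19.8 ± 11.3 CPM and Gabrb2 at 432 ± 19.9 against 847 ± 79.8 CPM (SD, n = 6). Steroid and thyroid hormone receptor genes were higher in lateral septum-like neurons in 6 of 8 cases with 2 not passing. This list turned with the way the medial class was drawn, to 3 lateral and 5 medial at clustering resolution 0.5 and to 2 and 4 without the rule on leading genes. Glutamate receptor genes divided 12 to 8 of 24 (12 and 9 adjusted over the list alone). Gria1 stood at 2794 ± 115 against 547 ± 98.1 CPM and Grik2 at 1476 ± 69.8 against 4035 ± 391 CPM (SD, n = 6).

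Potassium and HCN channel genes divided 11 lateral to 15 medial of 32 (12 and 16 adjusted over the list alone). This list turned to 15 and 13 with no mitochondrial limit, 16 and 14 at clustering resolution 0.5, 15 and 14 at 2.0 and also without the rule on leading genes. It turned to 13 and 11 with the lists left in the clustering and to 10 and 6 in thinned nuclei. Sodium and calcium channel genes divided 5 to 11 of 21 (6 and 11 adjusted over the list alone). Cacna1e stood at 1077 ± 40.8 against 261 ± 25.7 CPM (SD, n = 6). Synaptic adhesion genes divided 7 to 13 of 27. Ptprt stood at a log2 difference of 2.71 ± 0.09 and Ptprd at -1.84 ± 0.06 (SE, lateral minus medial, n = 6). Monoamine receptor genes divided 5 to 7 of 19 (8 and 8 adjusted over the list alone), led on the medial side by the adrenergic receptor Adra1b at -4.02 ± 0.17 on the log2 scale. That division turned to 8 and 5 with no mitochondrial limit, 8 and 7 at resolution 0.5 and 8 and 6 at 2.0. Of 5 acetylcholine receptor genes, 2 were higher in medial septum-like neurons, against 1 of 3 in lateral septum-like neurons with the lists left in the clustering. Chrm2 led at -1.80 ± 0.05 (SE, n = 6), and Chrm3, chosen after its value was seen, stood at -0.80.

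Neuropeptide receptor genes divided 5 to 9 of 26 (6 and 9 adjusted over the list alone), and turned to 11 and 6 with no mitochondrial limit, 11 and 7 at resolution 2.0 and 8 and 6 with the lists left in the clustering. Neuropeptide precursor genes divided 3 to 1 of 7, and 2 to 3 without the rule on leading genes. Penk, the enkephalin precursor, was higher in medial septum-like neurons at 19.8 ± 6.05 against 4.03 ± 0.642 CPM (SD, n = 6). Besides Nts and Sst, Tac1 was higher in lateral septum-like neurons by 1.51 on the log2 scale, named after its value was seen. Endocannabinoid genes divided 2 to 2 of 6. Daglb stood at 0.71 ± 0.13 and Mgll at -0.31 ± 0.09 on the log2 scale (SE, n = 6). For neuropeptide receptors, synaptic adhesion and endocannabinoid genes, the list's median, mean and test differed in sign.

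In edgeR's quasi-likelihood test 5872 of 14761 genes passed at the adjusted threshold, 3081 higher in lateral and 2791 higher in medial septum-like neurons, a balance that turned to 3681 against 3820 at clustering resolution 0.5. Adjusted p was 5.5e-30 for Casz1, 7.2e-11 for Egr3 and 4.8e-10 for Esr1 in that test, and apart from Sst, Crhr2 and Oxtr every gene named here had its direction in 6 of 6 samples. In limma's camera test 4 lists passed, with adjusted p of 0.00014 for immediate early genes, 3.3e-09 for cholesterol synthesis, 0.0109 for steroid receptors and 0.0120 for GABA receptors. All 4 calls were lost, with adjusted p = 0.128, 0.0655, 0.184 and 0.206 with an estimated correlation for these lists in turn. The medial septum-like class held 460 nuclei as drawn but 3106 at clustering resolution 0.5 and 1483 at 2.0. Besides Esr1 and Oprm1, the directions of Kcnh8 (-0.49 on the log2 scale at 0.5, against 2.47 as drawn) and Mgll (0.15 at 0.5) turned with it. Gabrg1 no longer passed at resolution 0.5 (0.03), Esr1 no longer passed at 2.0 (0.17), and Drd3 and Daglb no longer passed in thinned nuclei (1.14 and 0.65). Mgll no longer passed without replicate 6 (-0.25) or with no mitochondrial limit (-0.07).

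Lateral septum-like and striatal medium spiny-like neurons were both GABAergic by their markers. They differed in Cacna2d3, a calcium channel subunit gene, at 170 ± 20.9 against 2055 ± 185 CPM (SD, n = 6). Kcnd2, a potassium channel gene, stood at 1674 ± 78.2 against 7396 ± 515 CPM (SD, n = 6). The neuropeptide FF receptor gene Npffr2 (ENSMUSG00000035528) was at 0.923 ± 0.191 CPM in lateral septum-like and 40.4 ± 4.55 CPM in spiny-like neurons. The lipid transporter gene Abca12 stood at 0.0735 ± 0.0536 against 12.4 ± 3.14 CPM. Prkcd, which encodes protein kinase C delta, was higher in lateral septum-like neurons at 78.8 ± 3.82 against 5.85 ± 1 CPM. So were the transcription factor gene Prdm16 at 342 ± 18.8 against 25.8 ± 8.16 CPM and the transporter gene Abcb5 at 19.2 ± 2.15 against 1.31 ± 0.578 CPM (SD, n = 6). Sh3rf2 was higher in spiny-like neurons by a log2 difference of -5.46 ± 0.20 (SE, lateral minus spiny, n = 6). The opioid receptor Oprm1 was higher in spiny-like neurons at 268 ± 26.6 against 43.3 ± 2.21 CPM, as were the dopamine receptors Drd1 at 29.9 ± 4.36 against 2.32 ± 0.306 CPM and Drd3 at 74.0 ± 18.6 against 11.9 ± 1.85 CPM (SD, n = 6). The spiny-like class pooled clusters 11, 25 and 36 with 1230, 676 and 267 nuclei. Among these, Drd3 was a leading gene of cluster 36 only, whose share ranged from 0.298% of nuclei in replicate 3 to 0.819% in replicate 4. Clusters 11 and 36 had no spiny marker among their 10 leading genes. Likewise, none of the lateral septum-like clusters had a lateral septum marker among its leading genes. Their median marker level ranged from 0.164 of the highest cluster in cluster 34 to 0.662 in cluster 8. The make-up of either class may enter all values of this comparison.

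The other genes chosen in advance were higher in lateral septum-like neurons. Esr1 was at 18.5 ± 1.19 against 9.07 ± 2.75 CPM, Nts at 10.8 ± 4.19 against 3.09 ± 1.16 CPM and Crhr2 at 8.36 ± 0.677 against 3.20 ± 1.05 CPM (SD, n = 6). Sst stood at 3.54 ± 0.582 against 1.30 ± 0.811 CPM and Oxtr at 1.74 ± 0.391 against 0.327 ± 0.231 CPM (SD, n = 6). Adjusted p from edgeR was 0.000137 for the log2 difference of Oxtr, 2.21 ± 0.40 (SE, higher in 6 of 6 samples).

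Among neuropeptide receptor genes, 10 of 28 were higher in lateral septum-like and 13 in spiny-like neurons (10 and 15 adjusted over the list alone). The glucagon-like peptide receptor Glp1r stood at 10.5 ± 0.83 against 1.72 ± 0.623 CPM. Trhr, the thyrotropin-releasing hormone receptor, stood at 3.76 ± 0.835 against 40.2 ± 7.96 CPM (SD, n = 6). Neuropeptide precursor genes divided 3 to 6 of 10, with the dynorphin precursor Pdyn at 0.599 ± 0.318 against 11.6 ± 4.91 CPM. Monoamine receptor genes divided 4 to 9 of 20 (6 and 9 adjusted over the list alone). The serotonin receptor Htr7 stood at 138 ± 5.14 against 24.1 ± 9.58 CPM. Acetylcholine receptor genes divided 2 to 2 of 6 (3 and 2 adjusted over the list alone). Chrm3 stood at a log2 difference of 2.18 ± 0.06 and Chrm1 at -3.20 ± 0.11 (SE, n = 6). For steroid and thyroid hormone receptors the division was 5 to 2 of 8. Thra stood at 60.1 ± 1.95 against 83.1 ± 7.19 CPM. Endocannabinoid genes were higher in lateral septum-like neurons in 5 of 6 cases. The cannabinoid receptor Cnr1 stood at 47.8 ± 3.94 against 15.8 ± 2.65 CPM. The exception was Mgll at 34.1 ± 1.80 against 79.8 ± 10.6 CPM (SD, n = 6).

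Glutamate receptor genes divided 10 to 11 of 24. Grik1 stood at a log2 difference of 1.77 ± 0.08 and Grm3 at -1.73 ± 0.06. GABA receptor genes divided 8 to 4 of 16. Gabrg1 stood at 1.33 ± 0.07 and Gabrd at -2.23 ± 0.11 (SE, n = 6). Potassium and HCN channel genes divided 13 to 11 of 32 (15 and 12 adjusted over the list alone). Kcnt2 stood at 1.34 ± 0.05. Sodium and calcium channel genes divided 8 to 9 of 21, with Cacna2d2 at 1.62 ± 0.04. Synaptic adhesion genes divided 10 to 10 of 26 (11 and 10 adjusted over the list alone). Il1rapl2 stood at 2.70 ± 0.13 and Slitrk3 at -1.12 ± 0.11 (SE, n = 6). Cholesterol synthesis genes mostly did not pass, with 2 higher in each class and 16 of 20 not passing. The call of Cyp51 at 0.34 ± 0.07 (SE, n = 6) was lost in thinned nuclei at 0.23. The others, chosen after their values were seen, were Mvk at 0.82 in 6 of 6 samples, and Fdft1 at -0.34 and Fdps at -0.50, each in 5 of 6 samples. Immediate early genes did not pass in 11 of 13 cases, and adjusted over the list alone 0 passed. Also chosen after their values were seen, Egr4 was higher in lateral septum-like neurons by 0.81 (5 of 6 samples) and Nr4a3 in spiny-like neurons by -0.62 (4 of 6 samples). For acetylcholine receptors, potassium and HCN channels and cholesterol synthesis, the list's median, mean and test differed in sign.

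In edgeR's quasi-likelihood test 7193 of 14972 genes passed at the adjusted threshold, 3620 higher in lateral septum-like and 3573 higher in spiny-like neurons. The balance was 4334 against 3297 with no filter on low counts and turned to 3527 against 3589 with doublets kept. Adjusted p in that test was 6.3e-18 for Cacna2d3 and 1.1e-16 for Prkcd, and apart from Fdft1, Fdps, Egr4 and Nr4a3 the named genes had their direction in 6 of 6 samples. In limma's camera test 0 of 13 lists passed, 2 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.235. By contrast limma's fry, which asks whether a list's genes move on balance one way without comparing them with other genes, passed 9 lists.

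The neurotrophin receptor gene Ngfr (ENSMUSG00000000120) was higher in cholinergic-like than in other neurons at 17.9 ± 5.52 against 0.192 ± 0.0645 CPM (SD, n = 6). Npy, a neuropeptide precursor gene, stood at 27.6 ± 13.7 against 0.234 ± 0.0518 CPM. The cholinergic-like class also held the GABAergic markers Gad1 at 216 ± 64.5 CPM and Gad2 at 260 ± 33.2 CPM. Lateral septum-like neurons had 178 ± 5.66 and 270 ± 10.7 CPM of them (SD, n = 6). Nos1 and Maf were among its leading genes, but not with features centred per sample, where it held 288 nuclei. Other neurons may thus be mixed in, and whether Npy or Sst lay in the nuclei with Chat was not tested. Kcnc2 was higher in cholinergic-like neurons at 1552 ± 407 against 250 ± 19.5 CPM. So were the adrenergic receptor Adra1a at 252 ± 46.3 against 42.2 ± 4.66 CPM and the delta opioid receptor Oprd1 at 39.6 ± 11.3 against 3.48 ± 0.532 CPM (SD, n = 6). The metabotropic glutamate receptor Grm8 was lower at 154 ± 38.8 against 1181 ± 92.1 CPM and Prdm16 at 15.0 ± 10.2 against 261 ± 12.3 CPM (SD, n = 6). Genes with at most 3 counts in cholinergic-like neurons were Col6a3, higher in other neurons by a ratio of 30.9 (exact 95% interval 10.6 to 150.0), Itpka with a ratio of 34.1 (9.44 to 282) and Calcr with a ratio of 13.9 (4.75 to 67.4). These intervals cover counting error only.

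Cholesterol synthesis genes were higher in cholinergic-like neurons in 16 of 20 cases with 4 not passing (19 adjusted over the list alone). GABA receptor genes were lower, with 11 of 16 higher in other neurons and 5 not passing. Gabrg3 led at 1107 ± 189 against 2137 ± 45 CPM. Glutamate receptor genes were higher in cholinergic-like neurons in 4 and in other neurons in 14 of 24 cases. The receptor subunit Grin3a stood at 330 ± 42.2 against 144 ± 7.56 CPM (SD, n = 6). Steroid and thyroid hormone receptor genes were higher in other neurons in 5 of 8 cases with 3 not passing (6 adjusted over the list alone). Potassium and HCN channel genes divided 6 to 12 of 32 (7 and 13 adjusted over the list alone). Kcnh5 stood at a log2 difference of -2.23 ± 0.11 (SE, cholinergic minus other, n = 6). Sodium and calcium channel genes divided 5 to 8 of 21 (6 and 8 adjusted over the list alone). Cacna1e stood at -1.25 ± 0.08 (SE, n = 6).

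Monoamine receptor genes divided 5 to 6 of 20 (8 and 6 adjusted over the list alone). Drd3 stood at -2.41 ± 0.31 on the log2 scale. Acetylcholine receptor genes divided 2 to 1 of 6. Chrm2 stood at 1.34 ± 0.08 and Chrm3 at -1.78 ± 0.10 (SE, n = 6). Neuropeptide receptor genes divided 6 to 7 of 30 (6 and 8 adjusted over the list alone). Neuropeptide precursor genes divided 2 to 1 of 11 (2 and 2 adjusted over the list alone). Besides Npy these were, chosen after their values were seen, Sst, higher at 35.0 ± 44.4 against 2.97 ± 0.403 CPM with a wide spread between samples, and Nts, lower by a log2 difference of -3.21 (SD, n = 6). Synaptic adhesion genes divided 5 to 8 of 27 (6 and 8 adjusted over the list alone). Il1rapl2 stood at 2.25 ± 0.09 and Slitrk1 at -1.57 ± 0.16. Endocannabinoid genes divided 2 to 1 of 6 (2 and 2 adjusted over the list alone). Cnr1 stood at 0.70 ± 0.11 (SE, n = 6). Of 13 immediate early genes 11 did not pass, and Egr3 was lower in cholinergic-like neurons at 1.46 ± 1.71 against 11.1 ± 1.81 CPM (SD, n = 6). Nr4a3, chosen after its value was seen, was higher by 0.68 in 5 of 6 samples. For neuropeptide precursors and receptors, monoamine receptors, sodium and calcium channels, synaptic adhesion and endocannabinoid genes, the list's median, mean and test differed in sign.

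In edgeR's quasi-likelihood test 3049 of 15433 genes passed at the adjusted threshold, 1253 higher in cholinergic-like and 1796 higher in other neurons, but 1275 against 1249 by DESeq2. Adjusted p in that test was 8.3e-22 for Ngfr and 1.0e-24 for Npy, each in 6 of 6 samples, as for every gene named in this comparison but Nr4a3. In limma's camera test 2 lists passed. Cholesterol synthesis had an adjusted p of 1.1e-16 in camera, and the call held at adjusted p = 0.00301 with an estimated correlation. GABA receptors had an adjusted p of 0.00116 in camera, and the call was lost at adjusted p = 0.323 with an estimated correlation. The calls of Egr3 (-2.80 on the log2 scale), Calcr (-2.93) and Cnr1 (0.49) were lost in thinned nuclei, where 1013 of 10994 genes passed.

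Oligodendrocyte precursor-like nuclei differed from oligodendrocyte-like nuclei in the sialidase gene Neu4 (ENSMUSG00000034000) at 148 ± 10.1 against 0.994 ± 0.473 CPM (SD, n = 6). Inava stood at 70.8 ± 10.6 against 0.414 ± 0.253 CPM and the calcium-binding protein gene S100a2 at 59.0 ± 7.92 against 0.348 ± 0.132 CPM (SD, n = 6). Vipr2, a receptor for vasoactive intestinal peptide, stood at 33.4 ± 2.59 against 0.457 ± 0.238 CPM. The potassium channel gene Kcnh8 stood at 552 ± 28.1 against 13.1 ± 3.02 CPM and the glutamate receptor subunit gene Grin3a at 748 ± 35.8 against 29.3 ± 4.71 CPM (SD, n = 6). Oligodendrocyte-like nuclei were higher in the metabotropic receptor Grm3 at 2033 ± 78.2 against 68.5 ± 7.39 CPM and in Ptprd at 7226 ± 201 against 896 ± 29.5 CPM (SD, n = 6). They were also higher in the magnesium transporter family gene Nipal4 at 55.8 ± 2.25 against 0.244 ± 0.191 CPM (SD, n = 6). Galnt5, a glycosyltransferase gene, and Rab37, a small GTPase gene, had at most 3 counts in precursor-like nuclei and were higher in oligodendrocyte-like nuclei by ratios of 616.5 (exact 95% interval 170 to 5094) and 313.5 (56.0 to 12410).

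Synaptic adhesion genes were higher in precursor-like nuclei in 21 of 25 cases, with 3 higher in oligodendrocyte-like nuclei and 1 not passing. Ptprt led at 2058 ± 57.3 against 106 ± 19.0 CPM (SD, n = 6). Among genes at no less than 3 times the free RNA estimate, the same list held 20 genes divided 18 to 1. Sodium and calcium channel genes divided 18 to 1 of 20. Cacna2d3 led at 397 ± 14.5 against 49.9 ± 8.89 CPM. Only 7 genes of this list, all higher in precursor-like nuclei, lay at no less than 3 times the free RNA estimate. Potassium and HCN channel genes divided 21 to 7 of 28 and 9 to 5 of 14 above that level, with Kcna1 higher in oligodendrocyte-like nuclei at 227 ± 20.7 against 18.9 ± 2.79 CPM. Glutamate receptor genes divided 15 to 8 of 23 and 10 to 3 of 13 above it, and 5 of 5 acetylcholine receptor genes were higher in precursor-like nuclei, 3 of them above it. Chrna7 led at 41.0 ± 4.71 against 4.26 ± 1.45 CPM (SD, n = 6). GABA receptor genes divided 10 to 1 of 13, but 1 to 1 of 2 above it, so the 10 to 1 division did not stand clear of free RNA. Gabbr2 at 123 ± 9.04 against 22.2 ± 3.78 CPM lay at 2.04 times the estimate. Gabbr1 was higher in oligodendrocyte-like nuclei at 169 ± 9.35 against 63.9 ± 9.13 CPM.

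Cholesterol synthesis genes were higher in oligodendrocyte-like nuclei, the cells that make myelin, in 14 of 20 cases with 6 not passing. Insig1 led at 21.1 ± 1.97 against 4.73 ± 1.21 CPM (SD, n = 6). Steroid and thyroid hormone receptor genes divided 5 to 2 of 7, but 1 to 2 of 3 above 3 times the free RNA estimate. Thrb stood at a log2 difference of 2.16 ± 0.05 and Thra at -1.39 ± 0.05 (SE, precursor minus oligodendrocyte, n = 6). Neuropeptide receptor genes divided 4 to 1 of 5 and neuropeptide precursor genes 1 to 1 of 2, where the precursors were too few for a list test. Their pair, chosen after the values were seen, was Tac1 at 1.52 and Penk at -1.05 on the log2 scale. All 3 of 3 immediate early genes were higher in precursor-like nuclei, led by Nr4a1 at 2.46 ± 0.18, and 1 of the 3 lay above that level. Endocannabinoid genes divided 4 to 2 of 6 but 1 to 2 of 3 above it. Mgll stood at 2.30 ± 0.08 and Napepld at -1.83 ± 0.13. Monoamine receptor genes divided 3 to 2 of 7, with the histamine receptor Hrh1 at 4.02 ± 0.15 (SE, n = 6). Htr2c at 44.2 ± 11.2 against 71.2 ± 19.1 CPM and Scn9a at 11.8 ± 3.30 against 15.3 ± 3.56 CPM (SD, n = 6) passed as higher in oligodendrocyte-like nuclei but lay at 1.14 and 1.06 times the free RNA estimate. The call of Scn9a, at -0.37 ± 0.14 on the log2 scale (SE), was lost without replicate 1 (-0.32), replicate 4 (-0.29) or replicate 5 (-0.34), without the replicate block and with DESeq2.

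In edgeR's quasi-likelihood test 7683 of 11241 genes passed at the adjusted threshold, 3972 higher in precursor-like and 3711 higher in oligodendrocyte-like nuclei. Among genes at no less than 3 times the free RNA estimate the balance turned, with 2777 higher in precursor-like and 3585 in oligodendrocyte-like nuclei. Adjusted p in that test was 2.6e-32 for Grm3, 2.4e-28 for Neu4 and 0.0227 for Scn9a, with each named gene in its direction in 6 of 6 samples. In limma's camera test 7 of 12 lists passed, with adjusted p of 9.4e-06 for sodium and calcium channels, 9.5e-06 for synaptic adhesion, 0.000542 for cholesterol synthesis, 0.0018 for potassium and HCN channels, 0.00394 for GABA receptors, 0.0284 for acetylcholine receptors and 0.0382 for glutamate receptors. None of these 7 camera calls held with an estimated correlation (0 lists passed by this test, against 12 by limma's fry), where adjusted p = 0.200, 0.200, 0.106, 0.279, 0.313, 0.200 and 0.440 with an estimated correlation in the same order. The estimate was 8.7e-05 for cholesterol synthesis and 0.0095 for acetylcholine receptors, below the preset 0.01, so a higher correlation did not undo these calls. For the other lists that had passed it was 0.143 to 0.304. Median depth per sample was 5176 to 7047.5 UMIs in precursor-like and 2687 to 3894 UMIs in oligodendrocyte-like nuclei. Free RNA was estimated at 0.284 ± 0.0486 and 0.154 ± 0.0224 of the pooled profile (SD, n = 6).

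**Figure D3:**
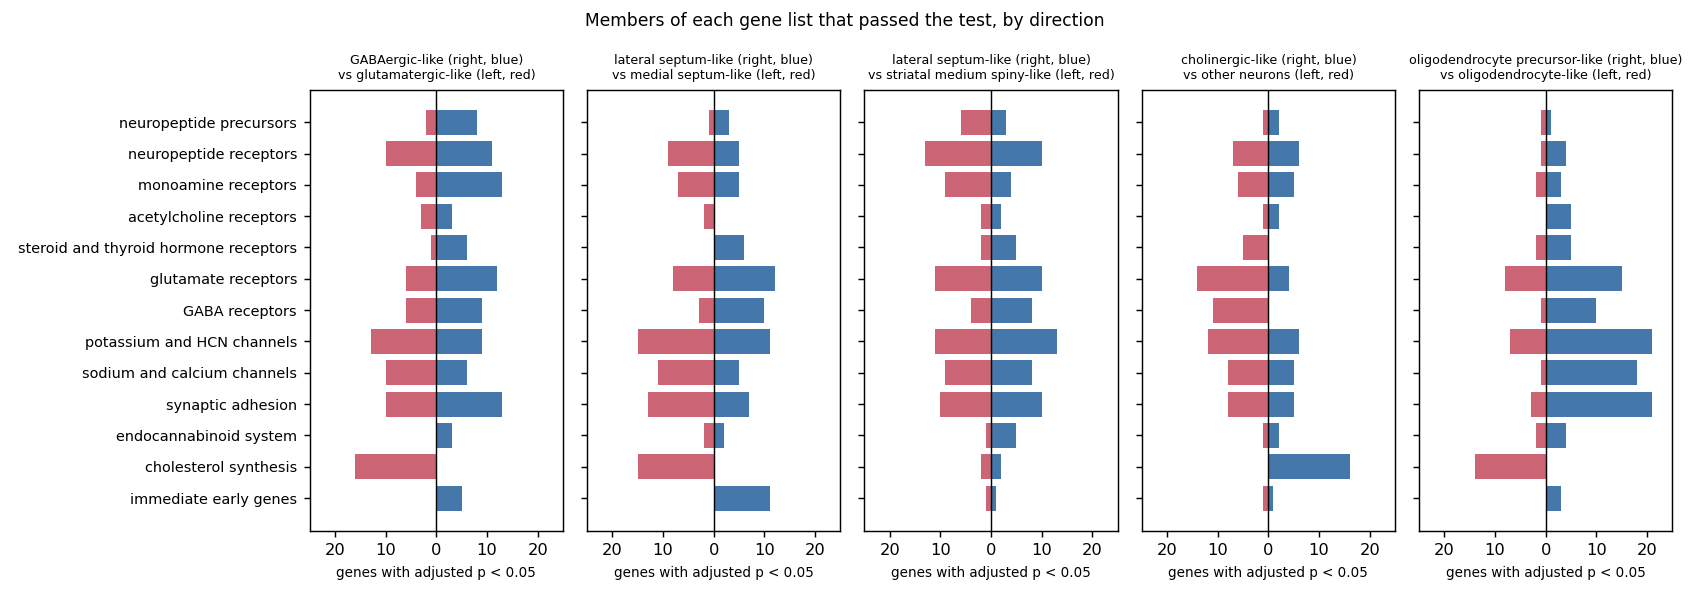
Members of each gene list that passed edgeR's test in each of the 5 comparisons, as bars counted in genes, with the first class of a comparison to the right in blue and the second to the left in red. Cholesterol synthesis genes lie on the glutamatergic-like side with 16 genes, the medial septum-like side with 15, the cholinergic-like side with 16 and the oligodendrocyte-like side with 14.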

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

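The label swaps, and the second tests of free RNA, of depth and of oligodendrocyte RNA, were tests chosen only after the result was seen, as were the first test of oligodendrocyte RNA and the pair of tests on the source of Chat and Crhr2.

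Class labels were swapped within samples in each comparison. Only 1 of 32 splits, the real one, reached its own count, with 5980 genes for GABAergic-like against glutamatergic-like neurons and a highest other count of 0. For lateral against medial septum-like neurons it was 1 of 32 with 5872 genes against 0, and for lateral septum-like against spiny-like neurons 1 of 32 with 7193 against 0. For cholinergic-like against other neurons it was 1 of 32 with 3049 against 0, and for precursor-like against oligodendrocyte-like nuclei 1 of 32 with 7683 against 0. Classes drawn from the same counts give this outcome by construction, so no conclusion is drawn from these splits.

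The first pattern weighed is the higher level of immediate early genes in lateral than in medial septum-like neurons. Free RNA could not be told apart by the first test, a median log2 ratio over oligodendrocyte-like nuclei of 1.221 ± 0.469 (SD, n = 6), but the second test argued against it, with the summed log2 ratio of 2.119 ± 0.415 exceeding the glial marker ratio of 0.545 ± 0.144 by 1.574 ± 0.477. Thinned nuclei gave 1.812 ± 0.748 against 1.533 ± 0.403 by medians and 1.921 ± 0.888 against 2.119 ± 0.415 by sums, with wide spreads. Because random thinning does not change the expected share of a gene within a nucleus, neither value can judge depth, which stays open. All these values used the 11 genes that had passed as higher in lateral septum-like neurons, which leans them to that side. For these genes the direction did not come from a few clusters, as 14 of 14 lateral septum-like clusters were higher in all 6 samples. Much of the size may, with cluster 29 at 429 CPM and cluster 10 at 153 CPM against 34.5 to 60.9 CPM in 10 clusters and 19.8 CPM in the medial class. The medial class was small and moved with naming, and no biological explanation was tested, because there is only 1 group and neither handling nor activity is given.

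The second is the higher level of cholesterol synthesis genes in cholinergic-like neurons. Oligodendrocyte RNA could not be judged from its markers, at -0.116 ± 0.139 (SD, n = 6), but the summed level of 462 ± 38.4 CPM lay above the 319 ± 12.4 CPM of oligodendrocyte-like nuclei themselves by a log2 ratio of 0.533 ± 0.135, which argues against it. Thinning lowered the median difference from 1.148 ± 0.153 to 0.704 ± 0.287. The summed ratio kept 1.057 ± 0.247 of 1.292 ± 0.121. Random thinning leaves the expected share of each gene within a nucleus unchanged. It also made counts sparse, with 1 UMI worth up to 13.5 CPM, which can move a median of log2 differences. Neither the median nor the summed ratio can thus judge depth, which stays open. Large nuclei in general were not the source, as 0 of 16 other neuronal clusters of equal or greater depth reached 80% of the level. These levels summed the 16 genes that passed as higher in cholinergic-like neurons, but over all 20 members, a sum added after the result was seen, the log2 ratio over oligodendrocyte-like nuclei was 0.48 ± 0.115 and the highest of those clusters had 321 against 499 ± 35.6 CPM (SD, n = 6), and no biological explanation was tested.

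The third is the concentration of Crhr2 in cluster 20, kept out of the lateral septum-like class by the rule on leading genes. The cluster also held Chat, and its ratio of Lhx8 to Chat over that of cholinergic-like nuclei, 0.2474 with a range of 0.089 to 0.39 over samples, could not rule out doublets or cholinergic nuclei. To bring that Chat, 44.3 ± 11.8% of cholinergic nuclei would be needed, and Lhx8 reached 0.239 ± 0.112 of the level they would carry (SD, n = 6). This restates nearly the same ratio with a bound chosen after the first test could not decide, so it is not separate evidence. With 0.085 to 0.376 over samples, Lhx8 fell short of what cholinergic nuclei as the only source of Chat would bring. A part of the Chat may still come from them. Crhr2 itself exceeded the next highest cluster, 26 at 37.6 ± 2.9 CPM, by a log2 ratio of 1.775 ± 0.132. Because cluster 20 was picked as the highest for Crhr2, such a lead was built in, and no conclusion on other clusters is drawn from it. Crhr2 exceeded oligodendrocyte-like nuclei by a log2 ratio of 5.778 ± 0.376, which argues against free RNA. Whether a neuron type with both genes exists stays open, and no biological explanation was tested.

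Of 177 groups of 6 values, 6 held a value lying apart from the others by more than the 5% critical value of Dixon's gap ratio, where chance marks about 1 in 20 groups. The cholinergic-like share was 0.849% in replicate 4 against 0.512 to 0.626% in the others. The endothelial-like share was 1.335% in replicate 2 against 1.757 to 1.982%. GABAergic-like neurons made up 31.76% in replicate 1 against 37.56 to 40.89%. Between precursor-like and oligodendrocyte-like nuclei, the log2 difference with 1 CPM added was -5.381 for Galnt5 in replicate 5 against -6.461 to -6.153. It was 5.048 for Vipr2 in replicate 6 against 4.417 to 4.527, and 2.384 for Chrna7 in replicate 2 against 3.124 to 3.199.

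Clusters without a name were left out of the comparisons. Cluster 7 held 1755 nuclei with a median of only 778 UMIs, with Rps29, Hbb-bs and mt-Co1 among its leading genes. Cluster 28 with 549 nuclei had markers of neuroblasts and of interneurons of caudal ganglionic origin, and cluster 32 with 394 nuclei markers of oligodendrocytes and their precursors, with Bcas1, Enpp6 and Tns3 among its leading genes. Mixed markers of glial lineages were found in cluster 37 with 244 nuclei (oligodendrocyte and microglia), cluster 41 with 82 nuclei (astrocyte and microglia), cluster 45 with 60 nuclei (astrocyte and oligodendrocyte) and cluster 46 with 51 nuclei (precursor and oligodendrocyte). The median share of added doublets among neighbours was 0.64, 0.71, 0.74 and 0.74 in these clusters, near the thresholds for removal of 0.72 to 0.80. Cluster 38 with 238 nuclei had microglial leading genes at a median of 15385.5 UMIs and a median share of 0.72. The named fibroblast-like and neuroblast-like clusters had 0.56 and 0.52. Cluster 40 with 116 nuclei was led by Ebf2 and Ebf3, cluster 43 with 65 nuclei by Top2a, cluster 44 with 62 nuclei by Bnc2 and Slc47a1, and cluster 47 with 43 nuclei by Mrc1 and F13a1.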

How the results depend on the processing

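The settings without the rule on leading genes and with genes at 3 times the free RNA estimate were tests chosen only after the result was seen. Of 104 other values of gene and list counts 96 stayed within a factor of 1.5 and 8 moved, and of 111 values of 16 class shares 103 stayed and 8 moved. Gene counts here took passing genes of any size. Between lateral and medial septum-like neurons, genes passing at over 2-fold numbered 2032 as drawn. They fell to 1255 with no mitochondrial limit, 1213 at resolution 0.5 and 1295 at 2. With lists left in they fell to 1246, and without the rule on leading genes to 1296. Of 2797 values of 143 named gene results 2753 stayed, 13 reversed, 20 became weaker and 11 stronger, the latter all Crhr2 and Oxtr between lateral and medial septum-like neurons. Some of these values could not move, which raises the number that stayed. The free RNA setting kept the log2 differences of the main fit by design. Without the rule on leading genes, classes changed only in the comparisons with lateral septum-like neurons. Thinned to 2000 UMIs, 2949 of 11130 genes passed between GABAergic-like and glutamatergic-like neurons, 1894 of 9933 between lateral and medial septum-like, 3446 of 10571 between lateral septum-like and spiny-like and 1013 of 10994 between cholinergic-like and other neurons, where fewer genes could be tested. With an estimated correlation camera passed 0 lists (from 5), 0 (from 4) and 1 (from 2) for GABAergic-like against glutamatergic-like, lateral against medial septum-like and cholinergic-like against other neurons, and 0 (from 7) between precursor-like and oligodendrocyte-like nuclei. All reversals lay between lateral and medial septum-like neurons, a class of 460 nuclei that grew to 1418 with no mitochondrial limit, 3106 at resolution 0.5, 1483 at 2, 1389 with lists left in the clustering and by the 1819 nuclei of cluster 5 without the rule on leading genes, so other nuclei entered it. Kcnh8 turned to -0.56 with no mitochondrial limit, -0.49 at resolution 0.5, -0.47 at 2 and -0.20 without the rule. Esr1 turned to -0.70 at resolution 0.5 and -0.84 without the rule, and Oprm1 to 0.18 with no mitochondrial limit, 0.092 at resolution 2 and 0.11 with lists left in. Mgll turned to 0.15 at resolution 0.5, 0.0195 at 2, 0.23 in thinned nuclei and 0.10 without the rule. Leaving out 1 replicate gave 5116 to 5874, 5175 to 5633, 6426 to 6773, 2657 to 2826 and 7308 to 7585 genes in the order of the comparisons, and dropping the replicate block 6216, 6173, 7174, 3339 and 7574. The share of passing genes that were higher in cholinergic-like neurons was 41.1% with TMM, 48.9% with RLE, 50.5% with DESeq2 and 29.9% in thinned nuclei, and that class was not found with lists left in the clustering, so no value exists there. With no mitochondrial limit and with lists left in, a cluster led by Gm28905 and Kcnmb2 was named medial septum-like, with 969 and 936 nuclei. As drawn, cluster 16 with these leading genes (1048 nuclei) was lateral septum-like, so the lateral class moved too. Beyond such changes in the nuclei named and in the genes tested, the cause was not tested.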

Other observations

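The comparisons among clusters below, which are not tests, were chosen only after the result was seen, with the highest cluster of each gene picked as the maximum of the same values.

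Among the 14 lateral septum-like clusters and cluster 20, which the rule on leading genes kept out of that class (14336 nuclei together), 30 of 180 list genes left out of the clustering stood more than 4-fold higher in their top cluster than in the remaining ones. Because the top cluster is the maximum, some excess is built in and no test is given. Tacr1, the substance P receptor gene, stood at 151 ± 36.6 CPM in cluster 24 against 8.59 ± 0.74 CPM elsewhere, so that 49.2% of its UMIs lay in 5.5% of the nuclei. Crhr2 stood at 131 ± 8.52 against 8.36 ± 0.677 CPM in cluster 20, and Cacna2d3 at 1264 ± 44.4 against 88.7 ± 15.3 CPM in cluster 18 (SD, n = 6). Esr1 and the neurokinin receptor Tacr3 peaked in the same cluster, 21, at 116 ± 19.5 against 11.6 ± 1.35 CPM and 36.2 ± 5.09 against 5.14 ± 0.962 CPM. Adra1a and Oprm1 peaked in cluster 34 at 287 ± 22.8 against 34.7 ± 3.83 CPM and 207 ± 41.7 against 40.8 ± 2.23 CPM (SD, n = 6). Calcr stood at 64.6 ± 11.4 against 7.72 ± 1.22 CPM in cluster 12, Drd3 at 49.8 ± 13.9 against 7.78 ± 1.07 CPM in cluster 14 and Oprk1 at 22.6 ± 2.98 against 3.62 ± 0.466 CPM in cluster 26 (SD, n = 6).

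Cluster 29, with 547 nuclei and Tafa1, Chga, Nr4a3, Kynu and Homer1 as leading genes, held the top level of 24 list genes, picked as the maximum. Among them were Nts at 63.9 ± 42.3 CPM, Sst at 21.7 ± 4.84 against 2.55 CPM elsewhere, Penk at 22.6 ± 6.74 against 3.02 CPM and Galr1 at 29.8 ± 7.38 against 3.05 CPM (SD, n = 6). Cluster 20, where Crhr2 was highest, also held Chat at 65.8 ± 11.2 CPM against 2.24 ± 0.437 CPM in lateral septum-like neurons and 152 ± 39.5 CPM in cholinergic-like neurons. Its choline transporter gene Slc5a7 stood at 17 ± 3.56 CPM and Lhx8 at 10.6 ± 4.79 CPM against 98.8 ± 16.3 CPM in cholinergic-like neurons (SD, n = 6).

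The level of immediate early genes in neurons differed between libraries, at 64.5, 62.3, 76.2, 80.9, 86.4 and 118 CPM for replicates 1 to 6, and nothing in the labels accounts for it. Xist stood at 0.314 to 0.396 CPM and the Y-linked gene Uty at 181 to 209 CPM in all 6 libraries, the pattern of male tissue.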
